A study of Schizosaccharomyces pombe with 8 samples.

How the data were processed

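RNA was measured in 8 samples of the fission yeast Schizosaccharomyces pombe, in 4 groups of 2: wild type (strain 972) and a strain deleted for pgr1, each untreated or treated with 1 mM hydrogen peroxide (H2O2) for 30 min. Per the labels, cells grew in YE5S, a rich yeast extract medium, at 30 °C to an OD600 of 0.5, RNA was extracted with hot phenol, and poly(A) RNA libraries were made with a TruSeq stranded mRNA kit. Per the submitters' processing notes, FastQC, Trimmomatic, Salmon and DESeq2 were used and the genome build was ASM294v2; versions, settings and the strand setting of the counting are not given in the sources used here.

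The deposited table holds, for 5165 genes, a signal that the authors made by dividing each gene's read count by a size factor of its library (DESeq2-normalized counts). It also has 1 line that names no gene, which was left out. The normalized counts of a library summed to between 10969093 and 14931323. In each library the values were whole multiples of the worth of 1 read, within a tolerance of 0.05 reads, for 99.98% to 100.0% of genes. The exception was meu1. The recovered reads came to between 12026222 and 14125543 per library, and 22 genes were at 0 in every library. Gene names came from a reference gene table of assembly ASM294v3, which is not the authors' build, so no coordinates are given. Of the gene identifiers, 5129 matched that table and 36 did not; 5097 matched a protein-coding gene and 32 a pseudogene.

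From the deposited values log2(value + 1) was computed, so a fold change understates the change of a gene with few reads. Genes with a value of at least 10 in at least 2 libraries were tested (5028 genes, 137 left out). limma 3.58.1 in R 4.3.3, with a trended prior variance, was fitted to all 8 libraries with 1 mean per group, which leaves 4 residual degrees of freedom shared by the groups. There were 5 comparisons: H2O2 against untreated in each strain, the mutant against wild type in each condition, and the difference between the strains' H2O2 responses. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method, and an adjusted p below 0.05 was called. Nothing in the labels says that the 2 libraries of a group came from separate cultures, and there was 1 deletion strain, so the p-values measure only the spread between these samples, which may be technical. The libraries of a group differed by more than the sampling of reads allows (chi-square per degree of freedom 21.7, 24.0, 18.1 and 7.8 for untreated and treated wild type and untreated and treated mutant), which separate library preparation also gives, so this does not show separate cultures.

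The design, the rule for the genes named, most alternatives and 28 gene lists were fixed before the data were examined, and the other alternatives were chosen after seeing the data. The lists were core stress response, Pap1 regulon, glutathione and glutaredoxin system, thioredoxin and peroxiredoxin system, superoxide and peroxide detoxification, iron uptake, iron-using proteins, iron-sulfur cluster assembly, cytosolic chaperones, mitochondrial chaperones and proteases, respiratory chain and ATP synthase, mitochondrial ribosome, cytosolic ribosomal proteins, ribosome biogenesis, sulfur assimilation and methionine, pentose phosphate and NADPH supply, lysine and leucine synthesis, proteasome, hexose transporters, glycolysis, S-phase genes, histones, cell separation, DNA repair, nitrogen starvation and sexual development (markers of another cell state), phosphate uptake, copper and zinc uptake, and strain marker genes. Of 552 entries, 546 were matched by symbol or synonym. The lists overlap. Lists with at least 3 tested members were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists within a comparison. camera with an estimated correlation and limma's fry were the alternatives. The name pattern of the ribosomal protein list also took in 3 subunits of RNase P (rpp1, rpp21, rpp40).

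Named genes were, per comparison, the 8 highest and 8 lowest log2 fold changes among called genes with a mean of at least 20 in a compared group and replicates that did not overlap between groups (not asked of the difference of responses), leaving out Tf2 transposons and non-coding RNAs. To these were added the 2 largest rises and 2 largest falls of each list and 22 genes of redox metabolism and strain markers. Genes beside the pgr1 locus were allowed as a check. Some named genes are not reported here, among them those at 0 in both libraries of a group. A gene is marked as uncertain where at least 5% of its 31-base stretches occur in another gene (211 of 5129 genes with sequence) or where over 50% of its exons lie opposite another gene (575 genes), because reads could not be assigned to strand with the information used here.

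The fit was tested on simulated counts with 200 genes changed by known folds. At a 2-fold change it recovered 92.5% of changed genes for H2O2 in wild type (5017 genes in the step), 94.0% for H2O2 in the mutant (5022), 100.0% for the untreated mutant (5015), 98.5% for the treated mutant (5016) and 89.6% for the difference of responses (5017). At a 1.5-fold change the shares were 86.6%, 77.6%, 86.6%, 89.6% and 49.3%, and at 4-fold 98.5%, 98.5%, 98.5%, 100.0% and 92.4%. Of 203, 194, 204, 205 and 172 calls, 18, 14, 14, 13 and 18 fell on unchanged genes, in each comparison a larger share than the threshold of 0.05 allows. Only 200 genes were changed in the simulation, far fewer than were called in the data. It therefore does not check the scaling or the share of false calls where many genes change. In each comparison a respiratory chain list shifted 2-fold was found by camera, together with 1 other list of the 28. The shifted list shares rip1, sdh4 and cyc1 with the iron-using list. Genes were simulated independently of each other, so the preset correlation of camera was not checked.

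For comparisons that share untreated wild-type libraries, 100 sets of unchanged groups were simulated. Alternatives were other pseudocounts (0.5 and 5), no filter or a mean of at least 50, TMM rescaling, median centring and quantile normalization, a fit of the compared groups alone, a prior variance with no trend, the replicate number as a term, leaving out each library, a log2 fold change of at least 1 as well, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads. Figures were drawn with matplotlib 3.10.9.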

Results

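Poly(A) RNA of fission yeast was sequenced in 8 libraries, 2 each of untreated wild type, wild type treated with 1 mM H2O2 for 30 min, an untreated pgr1 deletion mutant and the mutant treated in the same way. The gene pgr1 encodes glutathione reductase, which returns oxidised glutathione to its reduced form with electrons from NADPH. Recovered reads per library ranged from 12026222 to 14125543. Levels are the authors' DESeq2-normalized counts, and unless stated otherwise the value after a gene is its log2 fold change ± SE from limma on log2(value + 1), with n = 2 libraries in each group.

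The pgr1 transcript (SPBC17A3.07) was low in all 4 mutant libraries. Its normalized counts were 4939.4 and 4805.1 in untreated wild type, 7201.1 and 6792.4 in treated wild type, 159.1 and 91.4 in the untreated mutant, and 92.9 and 105.0 in the treated mutant. In the mutant pgr1 was at -5.32 ± 0.21 untreated (limma, Benjamini-Hochberg adjusted p = 1.86e-07) and was at -6.13 ± 0.21 after H2O2 (limma, Benjamini-Hochberg adjusted p = 1.32e-07). Of the genes beside the locus, SPBC17A3.08, of whose exons 77.6% lie opposite another gene, rose by 0.86 ± 0.08 untreated (limma, Benjamini-Hochberg adjusted p = 6.1e-05). The other, SPBC17A3.06, was at -0.40 ± 0.16 and did not pass (limma, Benjamini-Hochberg adjusted p = 0.0748).

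**Figure D1:**
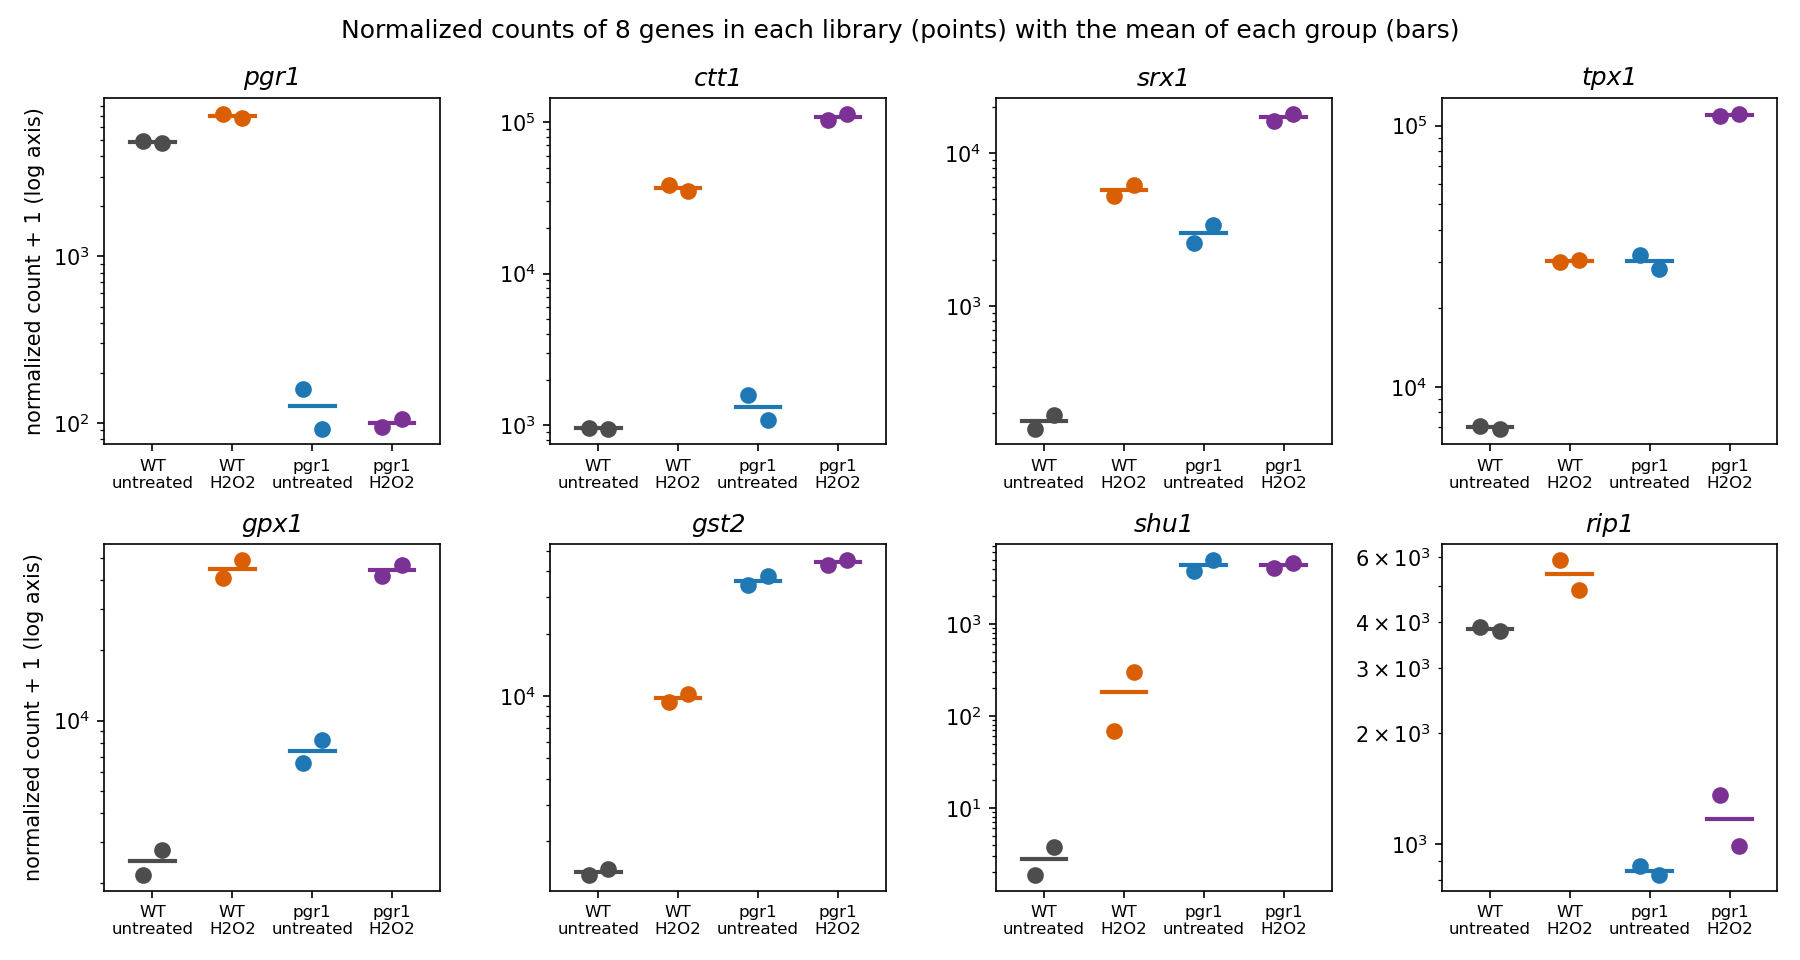
Normalized counts plus 1 (log axis) of 8 genes in each library (points) of the 4 groups on the horizontal axis, with group means (bars). The pgr1 counts of the 4 mutant libraries lie between 91.4 and 159.1, below the 4 wild-type libraries.

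The first comparison asks how wild-type cells respond to peroxide. Antioxidant enzymes rose: ctt1, the catalase, from 951.2 ± 3.11 to 36680.5 ± 2065.8 normalized counts (mean ± SD, n = 2), a log2 change of 5.27 ± 0.15. The sulfiredoxin gene srx1 rose by 5.01 ± 0.14, the glutathione peroxidase gene gpx1 by 4.18 ± 0.15, the peroxiredoxin gene tpx1 by 2.11 ± 0.09 and the thioredoxin reductase gene trr1 by 1.46 ± 0.08. The largest rises among named genes included ddr48 (9.28 ± 0.16), the phosphoketolase family gene SPBC24C6.09c (8.70 ± 0.18), lsd90 (8.53 ± 0.15) and ssd2, a succinate-semialdehyde dehydrogenase gene (7.64 ± 0.22). The phosphate transporter gene pho842 (-5.67 ± 0.22), the cell wall enzyme genes gas1 (-4.38 ± 0.19) and eng1 (-4.02 ± 0.20) and the chitinase gene cts2 (-3.74 ± 0.25) fell.

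Of the core stress genes, the targets of the stress kinase Sty1 and its factor Atf1, 19 of 20 rose (19 when adjusted over the list alone), with a median of 3.91, led by ish1 (6.05 ± 0.11) and the phosphatase gene pyp2 (5.62 ± 0.27). The list passed camera (adjusted p = 2.7e-09, adjusted p = 0.231 with an estimated correlation). In the Pap1 regulon, antioxidant targets of the factor Pap1, 11 of 13 members rose and none fell (11 when adjusted over the list alone), with a median of 1.65. The Pap1 list had camera adjusted p = 9.48e-05, and adjusted p = 0.365 with an estimated correlation. All 8 superoxide and peroxide detoxification genes rose (8 when adjusted over the list alone), among them the superoxide dismutase genes sod1 (1.00 ± 0.15) and sod2 (1.17 ± 0.06), with a list median of 1.55. The detoxification list had camera adjusted p = 8.23e-04, and adjusted p = 0.231 with an estimated correlation. Of the thioredoxin and peroxiredoxin genes 9 of 10 rose and trx2 fell (-0.38 ± 0.07), 10 when adjusted over the list alone. The thioredoxin list had camera adjusted p = 0.0029, and adjusted p = 0.455 with an estimated correlation. In the glutathione and glutaredoxin list 11 of 15 rose, including gst3 (4.15 ± 0.08), gst2 (2.79 ± 0.09) and the glutathione synthesis gene gcs1 (0.80 ± 0.06), and ggt1 and pcs2 fell (-0.86 ± 0.13 and -0.85 ± 0.09), 13 when adjusted over the list alone. The glutathione list had camera adjusted p = 0.0067, and adjusted p = 0.365 with an estimated correlation.

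Protein quality control moved the same way in treated wild type. All 22 proteasome genes rose (22 when adjusted over the list alone), with a median of 0.79 and the largest rises for rpt6 (1.34 ± 0.07) and pre1 (1.14 ± 0.10). The proteasome list had camera adjusted p = 9.47e-07, and adjusted p = 0.231 with an estimated correlation. Of the cytosolic chaperones 12 of 14 rose, led by ssa1 (5.25 ± 0.13) and hsp16 (4.49 ± 0.11), and ssz1 (-0.95 ± 0.07) and sks2 (-0.44 ± 0.11) fell, 14 when adjusted over the list alone. The cytosolic chaperone list had camera adjusted p = 0.00179, and adjusted p = 0.455 with an estimated correlation. Mitochondrial chaperones and proteases rose in 11 of 12 cases (11 when adjusted over the list alone), with hsp78 at 3.29 ± 0.11. The mitochondrial chaperone list had camera adjusted p = 0.0032, and adjusted p = 0.365 with an estimated correlation. In the pentose phosphate and NADPH list 8 of 11 rose, with zwf1 at 2.66 ± 0.10 and gnd1 at 1.77 ± 0.09, and 2 fell, 10 when adjusted over the list alone. The pentose phosphate list had camera adjusted p = 0.0436, and adjusted p = 0.455 with an estimated correlation.

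All 32 ribosome biogenesis genes fell with H2O2 in wild type (32 when adjusted over the list alone), with a median of -1.53 and imp4 at -2.35 ± 0.15. The ribosome biogenesis list had camera adjusted p = 6.81e-12, and adjusted p = 0.365 with an estimated correlation. All 9 cell separation genes fell (9 when adjusted over the list alone), among them eng1 and cts2. The cell separation list had camera adjusted p = 1.44e-04, and adjusted p = 0.455 with an estimated correlation. Of 141 cytosolic ribosomal protein genes 37 fell and 1 rose (27 when adjusted over the list alone), with a median of -0.16 (camera adjusted p = 0.00448, adjusted p = 0.764 with an estimated correlation). The riser, rpp40 (0.97 ± 0.07), belongs to RNase P. Respiratory chain and ATP synthase genes rose in 25 of 34 cases and fell in 3 (28 when adjusted over the list alone), with a median of 0.40 under the deposited scaling and 0.01, with 7 higher and 8 lower, under quantile normalization. The respiratory list had camera adjusted p = 0.00695, and adjusted p = 0.455 with an estimated correlation. Quantile normalization also gave smaller medians for proteasome genes (0.36, with 18 higher), cytosolic chaperones (0.87), mitochondrial chaperones (0.18, with 5 higher and 2 lower), glutathione genes (0.40) and pentose phosphate genes (0.65). It gave a larger fall for ribosomal protein genes (-0.58, with 131 lower).

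Other lists did not pass camera in treated wild type. Iron uptake had 6 of 11 members higher and none lower (camera adjusted p = 0.0576), and iron-using proteins had 1 higher and 5 lower of 10, with the iron transporter gene pcl1 at -3.00 ± 0.14. Of 13 iron-sulfur cluster assembly genes 5 were higher and 5 lower, of 50 mitochondrial ribosome genes 13 and 12, of 14 sulfur assimilation genes 5 and 8, and of 10 lysine and leucine synthesis genes 7 and 2. Of 7 hexose transporter genes 3 were higher and 3 lower, of 15 glycolysis genes 8 and 2 (2 and 7 under quantile normalization), of 11 S-phase genes 3 and 6, of 10 histone genes 2 and 2, and of 18 DNA repair genes 10 and 2, with mag2 at 4.19 ± 0.25. Of 17 markers of nitrogen starvation and sexual development 5 were higher and 9 lower, with ste11 at -3.02 ± 0.26, of 4 phosphate uptake genes 1 and 2, of 6 copper and zinc uptake genes 2 and 4, and of 6 strain marker genes 4 and 0. In all, 1894 of 5028 genes rose and 1741 fell (limma, Benjamini-Hochberg adjusted p below 0.05), 691 and 595 of them at least 2-fold. Under quantile normalization the balance turned, to 1646 higher and 2052 lower, and 31 genes called under both scalings changed sign.

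**Figure D2:**
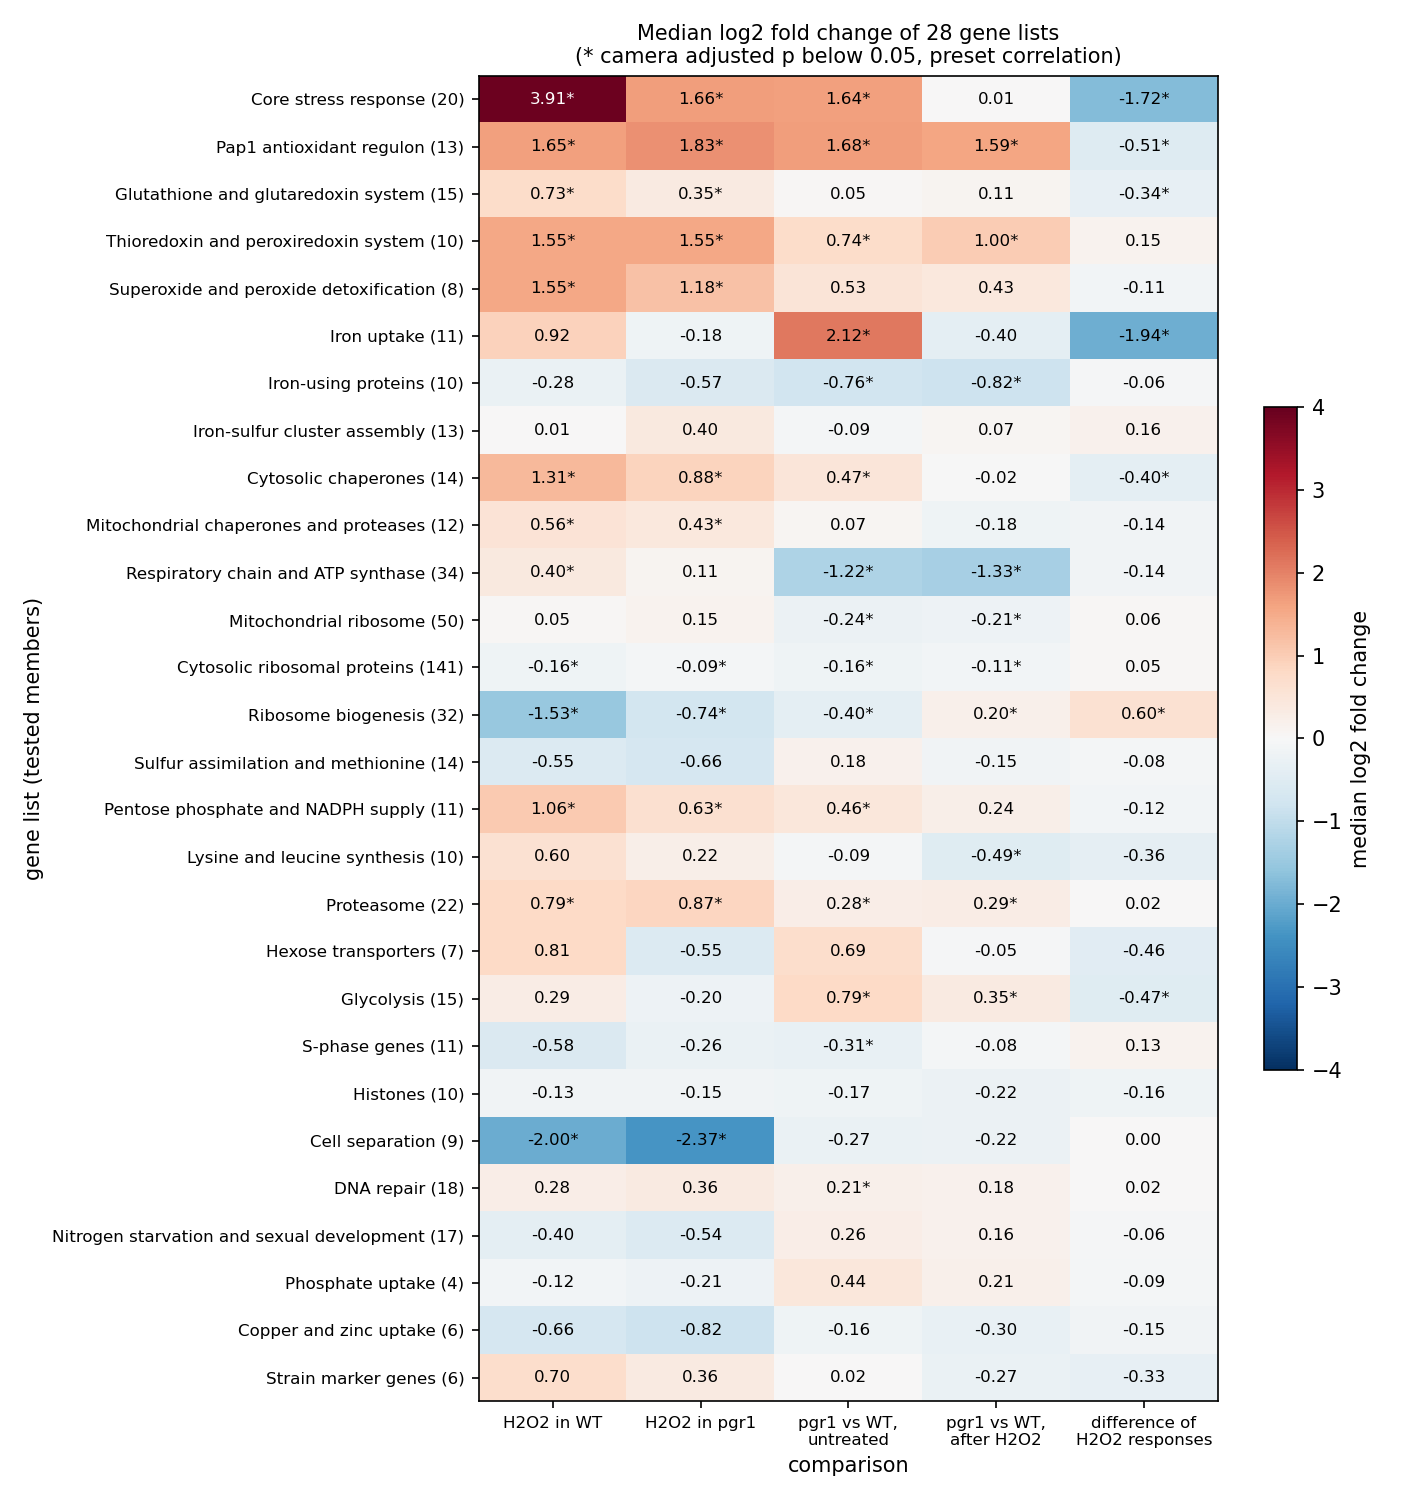
Median log2 fold change (colour and number) of the tested members of 28 gene lists (vertical axis, with member numbers) in the 5 comparisons (horizontal axis); an asterisk marks a camera adjusted p below 0.05 at the preset correlation. The core stress list has medians of 3.91, 1.66, 1.64, 0.01 and -1.72 from left to right; the sign of the medians that lie near 0 depends on the scaling, and the respiratory list stays at or below -1.22 in both comparisons of the mutant with wild type under 4 scalings.

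The same treatment was applied to the pgr1 mutant. The catalase gene ctt1 rose from 1325.6 ± 351.4 to 108053.9 ± 7225.5 normalized counts (mean ± SD, n = 2), a log2 change of 6.37 ± 0.15. The thioredoxin reductase gene trr1 rose by 3.06 ± 0.08, srx1 by 2.52 ± 0.14, gpx1 by 2.58 ± 0.15 and tpx1 by 1.87 ± 0.09, while gst2 rose by 0.29 ± 0.09 under the deposited scaling and was at -0.25 under quantile normalization. As in wild type, gas1 (-4.03 ± 0.19) and pho842 (-3.95 ± 0.22) fell. The calcium ATPase gene cta3 fell by 4.09 ± 0.61 on the log2 scale. In all, 1793 genes rose and 1634 fell (limma, Benjamini-Hochberg adjusted p below 0.05), 487 and 397 of them at least 2-fold. Under quantile normalization the balance turned as well, to 1588 higher and 1795 lower, with 27 changes of sign.

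In the treated mutant 18 of 20 core stress genes rose and 1 fell (19 when adjusted over the list alone), with a median of 1.66. The core stress list had camera adjusted p = 5.89e-07, and adjusted p = 0.288 with an estimated correlation. The Pap1 regulon had 11 of 13 members higher and pmd1 (-0.48 ± 0.08) and bfr1 (-0.36 ± 0.09) lower (13 when adjusted over the list alone), with a median of 1.83. The Pap1 list had camera adjusted p = 0.00109, and adjusted p = 0.429 with an estimated correlation. All 10 thioredoxin and peroxiredoxin genes rose (10 when adjusted over the list alone, camera adjusted p = 1.38e-04, adjusted p = 0.429 with an estimated correlation), as did all 8 superoxide and peroxide detoxification genes (8 when adjusted over the list alone, camera adjusted p = 2.72e-04, adjusted p = 0.239 with an estimated correlation). All 22 proteasome genes rose (22 when adjusted over the list alone), with a median of 0.87. The proteasome list had camera adjusted p = 3.35e-08, and adjusted p = 0.239 with an estimated correlation. Of 14 cytosolic chaperones 10 rose, led by ssa1 (2.74 ± 0.13), and 2 fell, 12 when adjusted over the list alone. The cytosolic chaperone list had camera adjusted p = 0.00577, and adjusted p = 0.527 with an estimated correlation.

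Ribosome biogenesis genes fell in 26 of 32 cases in the treated mutant (28 when adjusted over the list alone), with a median of -0.74. The ribosome biogenesis list had camera adjusted p = 3.35e-08, and adjusted p = 0.429 with an estimated correlation. All 9 cell separation genes fell (9 when adjusted over the list alone), with a median of -2.37. The cell separation list had camera adjusted p = 2.73e-05, and adjusted p = 0.429 with an estimated correlation. Glutathione and glutaredoxin genes rose in 9 of 15 cases and fell in 2 (11 when adjusted over the list alone, camera adjusted p = 0.0307, adjusted p = 0.429 with an estimated correlation), and mitochondrial chaperones rose in 8 of 12 (8 when adjusted over the list alone, camera adjusted p = 0.0195, adjusted p = 0.429 with an estimated correlation). Pentose phosphate genes rose in 7 of 11 cases and fell in 1 (8 when adjusted over the list alone, camera adjusted p = 0.044, adjusted p = 0.456 with an estimated correlation), and ribosomal protein genes fell in 32 of 141 and rose in 4 (19 when adjusted over the list alone, camera adjusted p = 0.0256, adjusted p = 0.799 with an estimated correlation). Under quantile normalization the medians in the treated mutant were 0.49 for proteasome genes, 0.50 for cytosolic chaperones, 0.14 for mitochondrial chaperones, 0.19 for glutathione genes, 0.24 for pentose phosphate genes and -0.46 for ribosomal protein genes (120 lower). Iron uptake genes did not pass as a list (4 higher, 5 lower of 11), with the iron transport genes fio1 (-3.62 ± 0.42) and fip1 (-3.45 ± 0.51) lower.

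The third comparison asks what the loss of pgr1 changes in unstressed cells. Transcripts of the respiratory chain fell and those of iron uptake rose: rip1, the Rieske iron-sulfur protein of complex III, was at -2.18 ± 0.14, and its complex III partners qcr7 and qcr8 were at -2.05 ± 0.08 and -1.78 ± 0.11, with cyt1 at -1.74 ± 0.09. The cytochrome oxidase assembly gene coa2 fell by 2.22 ± 0.33 on the log2 scale. The heme transporter gene shu1 had 0.875 and 2.73 normalized counts in untreated wild type and 3762.1 and 4962.5 in the untreated mutant. Other genes that rose without H2O2 were ddr48 (5.71 ± 0.16), the metallothionein gene zym1 (5.47 ± 0.18), the flavin oxidoreductase gene SPBC23G7.10c (5.34 ± 0.17), gst2 (4.66 ± 0.09) and srx1 (4.07 ± 0.14). The exons of rip1 lie wholly opposite another gene, so its value is uncertain.

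All 34 respiratory chain and ATP synthase genes fell in the untreated mutant (34 when adjusted over the list alone), with a median of -1.22. The respiratory list had camera adjusted p = 2.84e-24, and adjusted p = 0.16 with an estimated correlation. The medians were -0.73 for the 4 members of complex II, -1.72 for 9 of complex III, -1.24 for 8 of complex IV and -1.10 for 11 of ATP synthase. Genes of the mitochondrial genome are not in this list, so the complexes are covered only in part. The 11 mitochondrial identifiers reached at most 38.2 normalized counts, and 2 passed the filter. Of the proteins that use iron, the list repressed by the factor Php4, 8 of 10 fell and none rose (10 when adjusted over the list alone), with cyc1, cytochrome c, at -1.41 ± 0.12. The iron-using list had camera adjusted p = 1.06e-05, and adjusted p = 0.308 with an estimated correlation. All 11 iron uptake genes, repressed by the factor Fep1, rose (11 when adjusted over the list alone), with a median of 2.12 and str3 at 3.59 ± 0.61. The iron uptake list had camera adjusted p = 5.19e-06, and adjusted p = 0.308 with an estimated correlation. The wild-type libraries stood apart on these genes, with normalized counts of fip1 at 1032.2 and 2608.1 untreated and 1114.6 and 3347.2 after H2O2, and of str3 at 313.4 and 1076.6 untreated. Of 50 mitochondrial ribosome genes 23 fell and 2 rose (26 when adjusted over the list alone), with a median of -0.24 (-0.38 under quantile normalization) and mrpl16 at -1.14 ± 0.08. The mitochondrial ribosome list had camera adjusted p = 1.52e-06, and adjusted p = 0.308 with an estimated correlation.

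**Figure D3:**
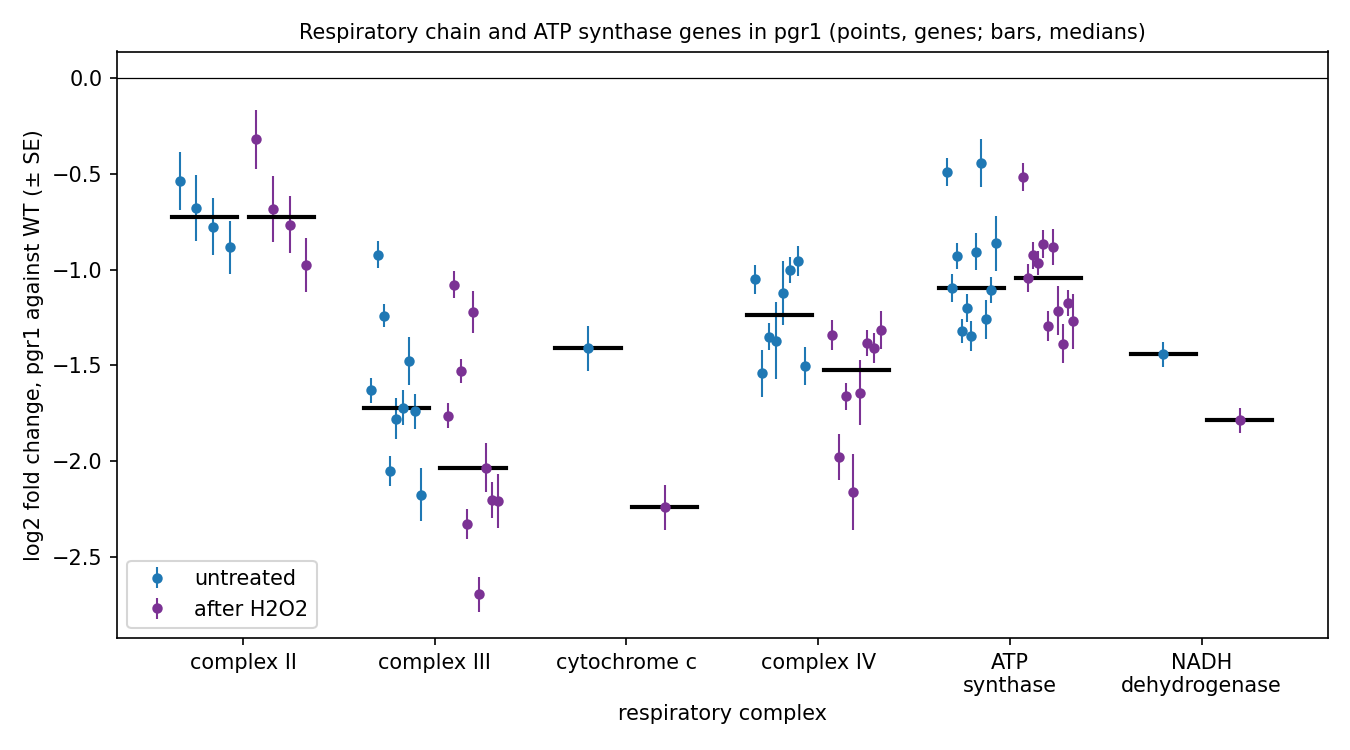
Log2 fold change of the mutant against wild type (vertical axis, ± SE) for genes of each respiratory complex (horizontal axis), untreated and after H2O2; bars are medians. The medians for complex III are -1.72 untreated and -2.04 after H2O2, and all points lie below 0.

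Core stress genes rose in 18 of 20 cases in the untreated mutant and none fell (18 when adjusted over the list alone), with a median of 1.64 and cta3 at 5.23 ± 0.61. The core stress list had camera adjusted p = 4.56e-12, and adjusted p = 0.163 with an estimated correlation. All 13 members of the Pap1 regulon rose (13 when adjusted over the list alone), with a median of 1.68 and caf5 at 4.65 ± 0.11. The Pap1 list had camera adjusted p = 4.11e-11, and adjusted p = 0.227 with an estimated correlation. Of the thioredoxin and peroxiredoxin genes 8 of 10 rose (8 when adjusted over the list alone), with tpx1 at 2.11 ± 0.09. The thioredoxin list had camera adjusted p = 8.95e-05, and adjusted p = 0.308 with an estimated correlation. The catalase gene ctt1 rose by 0.45 ± 0.15 (limma, Benjamini-Hochberg adjusted p = 0.0416). The glutathione list did not pass (7 higher and 1 lower of 15; camera adjusted p = 0.0545), although gpx1 (1.57 ± 0.15), grx1 (1.17 ± 0.16) and gcs1 (0.64 ± 0.06) rose and grx5, the mitochondrial glutaredoxin gene, fell (-0.48 ± 0.10). Superoxide and peroxide detoxification did not pass either (6 higher, 2 lower of 8; camera adjusted p = 0.0645), with sod2, the mitochondrial superoxide dismutase gene, lower (-0.39 ± 0.06).

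Glycolysis genes rose in 14 of 15 cases in the untreated mutant (14 when adjusted over the list alone), with a median of 0.79, led by gpd3 (4.69 ± 0.21), which shares 24.0% of its 31-base stretches with another gene, and by eno102 (3.23 ± 0.23). The glycolysis list had camera adjusted p = 2.24e-07, and adjusted p = 0.308 with an estimated correlation. Cytosolic chaperones rose in 9 of 14 cases and 1 fell (10 when adjusted over the list alone), with hsp16 at 3.69 ± 0.11. The cytosolic chaperone list had camera adjusted p = 0.00267, and adjusted p = 0.374 with an estimated correlation. Proteasome genes rose in 14 of 22 cases (18 when adjusted over the list alone, camera adjusted p = 1.26e-04, adjusted p = 0.308 with an estimated correlation). In the pentose phosphate list 6 of 11 rose and 1 fell (8 when adjusted over the list alone, camera adjusted p = 0.018, adjusted p = 0.308 with an estimated correlation), with zwf1 at 1.68 ± 0.10. DNA repair genes rose in 7 of 18 cases and 1 fell (10 when adjusted over the list alone, camera adjusted p = 0.0246, adjusted p = 0.372 with an estimated correlation), with the DNA glycosylase genes mag2 (3.36 ± 0.25) and mag1 (0.98 ± 0.10) higher. Ribosome biogenesis genes fell in 27 of 32 cases (30 when adjusted over the list alone), with a median of -0.40. The ribosome biogenesis list had camera adjusted p = 2.19e-10, and adjusted p = 0.308 with an estimated correlation. Ribosomal protein genes had 22 of 141 lower and 1 higher (1 when adjusted over the list alone, camera adjusted p = 7.15e-05, adjusted p = 0.522 with an estimated correlation), and S-phase genes 4 of 11 lower (4 when adjusted over the list alone, camera adjusted p = 0.00736, adjusted p = 0.374 with an estimated correlation).

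In the untreated mutant 1145 genes rose and 792 fell (limma, Benjamini-Hochberg adjusted p below 0.05), 283 and 50 of them at least 2-fold. The split depended on the scaling: 988 were higher and 1095 lower after median centring, and 980 higher and 1443 lower after quantile normalization. The 792 lower genes became 470 without replicate 1 of the untreated mutant and 484 without replicate 2 of untreated wild type. None of the 6 strain marker genes was called (ura4 -0.17 ± 0.08, leu1 0.14 ± 0.15, ade6 0.13 ± 0.08), with no call when adjusted over the list alone. After H2O2, 1 of them was higher and 3 were lower in the mutant than in wild type, with a median of -0.27 (camera adjusted p = 0.204). In the difference of responses 2 were lower (camera adjusted p = 0.238).

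The untreated mutant was also set against the H2O2 response of wild type, gene by gene. Of the genes higher in the mutant, 848 were also higher with H2O2 in wild type, where independent lists would share 431.3. Of those lower in the mutant, 453 were also lower with H2O2, where independent lists would share 274.2. Opposite calls numbered 128 (higher in the mutant, lower with H2O2) and 156 (the reverse). Across 5028 genes, which are not independent replicates, Pearson's r between the 2 sets of log2 fold changes was 0.54, with 0.48 in the simulated unchanged groups, because both comparisons use the untreated wild-type libraries. The covariance was 0.458 against a simulated 0.0173, a difference of 0.44. Against the mean response of both strains, where noise that is equal in the untreated libraries of both strains cancels, r was 0.47 (simulated -0.02) and the covariance 0.338 (simulated -6e-04). The simulation gave all libraries the same spread per gene, so its covariance was near zero by construction. In the data the SD of the log2 difference between libraries was 0.394 for untreated wild type and 0.248 for the untreated mutant, so the noise may cancel only in part. The 2 untreated wild-type libraries were not split between the comparisons, so part of the excess overlap may come from the shared controls.

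**Figure D4:**
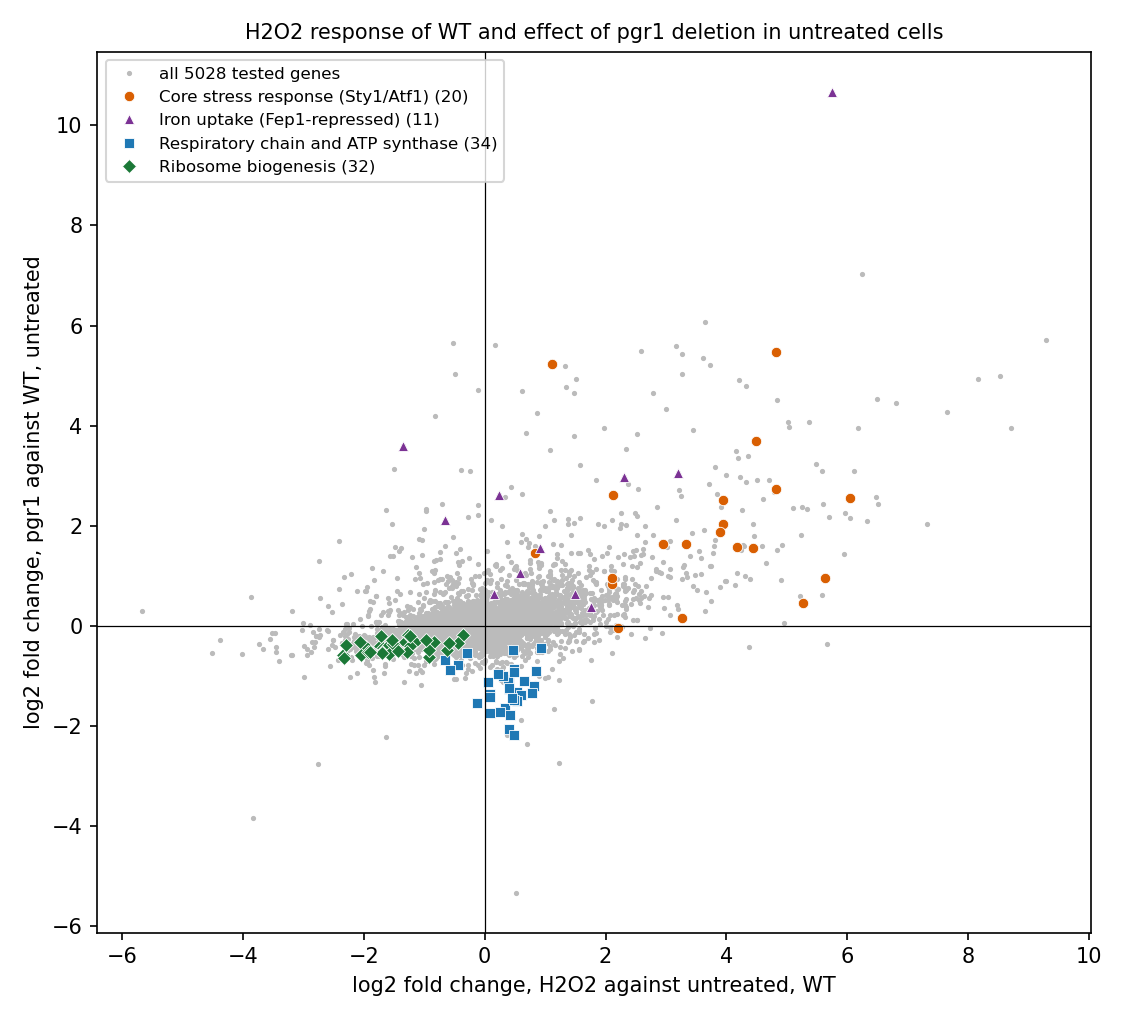
Log2 fold change with H2O2 in wild type (horizontal axis) and of the mutant against wild type, untreated (vertical axis), for 5028 genes (grey) and 4 gene lists (coloured). Core stress genes lie to the upper right (medians 3.91 and 1.64), and respiratory genes lie below 0 on the vertical axis (median -1.22).

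The fourth comparison sets the mutant against wild type after H2O2 in both. Genes higher in the mutant included the dehydrogenase gene osr1 (5.46 ± 0.08), the alcohol dehydrogenase gene adh8 (4.88 ± 0.14), the hydrolase gene hhy1 (4.49 ± 0.26) and SPCC18B5.02c (5.08 ± 0.13). The value for osr1 is uncertain, because it shares 16.7% of its 31-base stretches with SPCC663.08c, which was also higher (4.68 ± 0.09). The catalase gene ctt1 (1.56 ± 0.15), trr1 (2.29 ± 0.08), tpx1 (1.86 ± 0.09) and srx1 (1.59 ± 0.14) were higher in the treated mutant, and gst2 too (2.16 ± 0.09). Lower genes included qcr9 of complex III (-2.70 ± 0.09), 81.8% of whose exons lie opposite another gene, and cyc1 (-2.24 ± 0.12), together with SPCC70.08c (-2.68 ± 0.33) and SPBC1271.08c (-2.57 ± 0.13).

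Of the respiratory chain and ATP synthase genes 33 of 34 fell (33 when adjusted over the list alone), with a median of -1.33 (camera adjusted p = 9.05e-22, adjusted p = 0.195 with an estimated correlation), and 7 of 10 iron-using genes fell (7 when adjusted over the list alone, camera adjusted p = 5.39e-04, adjusted p = 0.743 with an estimated correlation). The complex medians were -0.72 for complex II, -2.04 for III, -1.53 for IV and -1.04 for ATP synthase. The Pap1 regulon was higher in 12 of 13 cases, with gst3 lower (-0.44 ± 0.08), 13 when adjusted over the list alone, and had a median of 1.59. The Pap1 list had camera adjusted p = 2.41e-07, and adjusted p = 0.52 with an estimated correlation. Thioredoxin and peroxiredoxin genes were higher in 9 of 10 cases, with pmp20 lower (-0.48 ± 0.12), 10 when adjusted over the list alone. The thioredoxin list had camera adjusted p = 3.49e-04, and adjusted p = 0.743 with an estimated correlation. Proteasome genes were higher in 15 of 22 cases (15 when adjusted over the list alone, camera adjusted p = 3.49e-04, adjusted p = 0.52 with an estimated correlation), glycolysis genes in 10 of 15 (11 when adjusted over the list alone, camera adjusted p = 0.00237, adjusted p = 0.743 with an estimated correlation) and ribosome biogenesis genes in 16 of 32, with 3 lower (20 when adjusted over the list alone, camera adjusted p = 0.00841, adjusted p = 0.743 with an estimated correlation).

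Lysine and leucine synthesis genes fell in 6 of 10 cases (6 when adjusted over the list alone, camera adjusted p = 0.00447, adjusted p = 0.743 with an estimated correlation), with lys3 at -0.88 ± 0.09. Mitochondrial ribosome genes fell in 23 of 50 cases and 5 rose (28 when adjusted over the list alone, camera adjusted p = 0.0022, adjusted p = 0.743 with an estimated correlation), and ribosomal protein genes fell in 17 of 141 and 6 rose (6 when adjusted over the list alone, camera adjusted p = 0.0359, adjusted p = 0.879 with an estimated correlation). The core stress list did not pass: 6 of 20 members were higher and 3 lower, with a median of 0.01 (-0.12 under quantile normalization, camera adjusted p = 0.679). Iron uptake did not pass either (3 higher, 4 lower of 11), and its median of -0.40 had the opposite sign to its mean of 0.36 and to the direction of the test. In all, 1334 genes were higher and 1128 lower (limma, Benjamini-Hochberg adjusted p below 0.05), a total of 2462. The majority depended on the scaling, with 1107 higher and 1362 lower after median centring and 1064 and 1238 after quantile normalization. Without replicate 2 of the treated mutant the total was 1628, with 872 higher.

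The last comparison tests whether the H2O2 response itself differed between the strains, where a negative value is a smaller rise or a larger fall in the mutant. The value was negative for ddr48 (-6.01 ± 0.22), lsd90 (-5.69 ± 0.21), hsp16 (-3.38 ± 0.15), zym1 (-3.99 ± 0.26) and gst2 (-2.50 ± 0.12), and positive for the putative glutathione transferase gene gst4 (3.05 ± 0.15), for sec72 (2.64 ± 0.13), for trr1 (1.60 ± 0.12) and for ctt1 (1.11 ± 0.21). Of the core stress genes 18 of 20 had a lower value in the mutant and 1 a higher one (19 when adjusted over the list alone), with a median of -1.72. The core stress list had camera adjusted p = 3.44e-12, and adjusted p = 0.32 with an estimated correlation. Ribosome biogenesis genes fell less in the mutant in 24 of 32 cases (27 when adjusted over the list alone), with a median of 0.60 and enp2 at 1.63 ± 0.15. The ribosome biogenesis list had camera adjusted p = 1.34e-13, and adjusted p = 0.786 with an estimated correlation. The iron uptake list had 9 of 11 members lower (10 when adjusted over the list alone), with a median of -1.94 and the ferric reductase gene frp1 at -4.17 ± 0.51. The iron uptake list had camera adjusted p = 6.9e-06, and adjusted p = 0.786 with an estimated correlation.

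The value was lower for 8 of 13 Pap1 regulon members and higher for 2 (10 when adjusted over the list alone, camera adjusted p = 0.0131, adjusted p = 0.786 with an estimated correlation), and lower for 8 of 14 cytosolic chaperones and higher for 1 (9 when adjusted over the list alone, camera adjusted p = 0.00238, adjusted p = 0.786 with an estimated correlation). It was lower for 7 of 15 glutathione and glutaredoxin genes and higher for 1 (8 when adjusted over the list alone, camera adjusted p = 0.0242, adjusted p = 0.786 with an estimated correlation), and lower for 3 of 15 glycolysis genes (10 when adjusted over the list alone, camera adjusted p = 0.0107, adjusted p = 0.786 with an estimated correlation). Genes raised at least 2-fold by H2O2 were chosen, after seeing the data, on the mean response of both strains, which favours neither strain. Of these 585 genes, 351 had a smaller and 34 a larger response in the mutant, 420 were higher and 17 lower in the untreated mutant, and after H2O2 213 were higher and 155 lower than in wild type. Of the 487 genes chosen on the mutant's own response, which favours a larger response there, 243 had a smaller and 71 a larger one. In all, the response differed for 1372 genes, 605 with a higher and 767 with a lower value in the mutant (limma, Benjamini-Hochberg adjusted p below 0.05). Under quantile normalization 651 were higher and 632 lower. The total was 909 (489 lower) without replicate 1 of the treated mutant and 781 (317 higher, 464 lower) without its replicate 2.

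**Figure D5:**
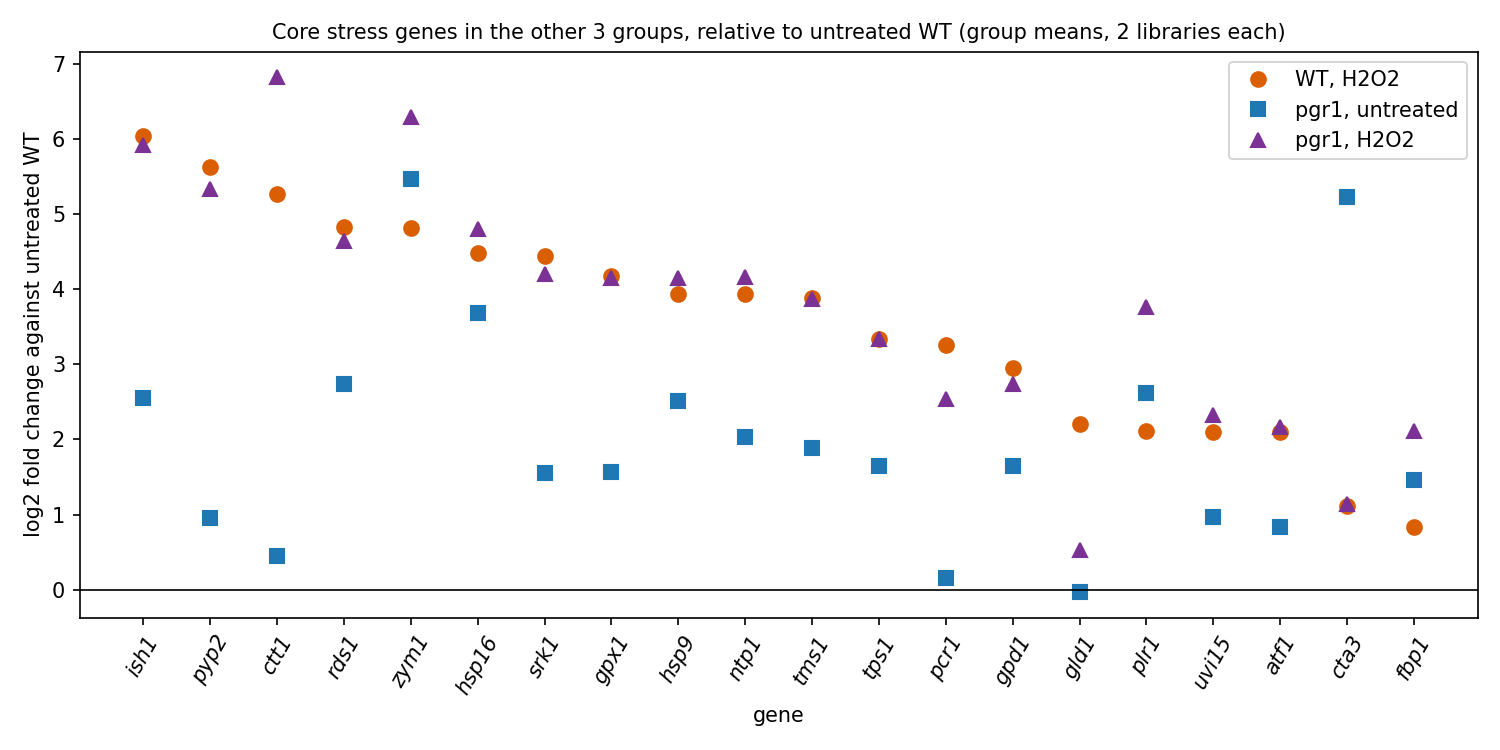
Log2 fold change of 20 core stress genes (horizontal axis) relative to untreated wild type (vertical axis) in treated wild type, the untreated mutant and the treated mutant (means of 2 libraries each). The median of the mutant's difference from wild type is 1.64 untreated and 0.01 after H2O2, and the second value is -0.12 under quantile normalization.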

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

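The tests of explanations in this part were chosen after the results were seen. The comparisons themselves were planned: the values of the next paragraph and the last pattern come from the difference between the strains' H2O2 responses, and the other patterns from the untreated mutant against wild type.

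The H2O2 response differed between the strains for 1372 genes. The median differences of response (mutant minus wild type, log2) of the lists that passed were -1.72 for core stress genes, -0.51 for the Pap1 regulon, -0.34 for glutathione and glutaredoxin genes (-0.20 under quantile normalization), -1.94 for iron uptake, -0.40 for cytosolic chaperones, 0.60 for ribosome biogenesis and -0.47 for glycolysis. None of these lists passed camera with an estimated correlation (adjusted p = 0.32 for core stress genes and 0.786 for the other lists). Lower values in the mutant for single genes were ddr48 -6.01, lsd90 -5.69, cta3 -5.21, SPAPB1A11.03 -5.03, frp1 -4.17, zym1 -3.99, hsp16 -3.38, ssa1 -2.51, gst2 -2.50, srx1 -2.49, eno102 -1.77, gpx1 -1.59, gst3 -1.25, grx1 -0.79, pgk1 -0.73 and grx4 -0.71. The values for shu1 (-5.75) and SPAC3G6.07 (-5.06) depend on the pseudocount, because untreated wild type averaged 1.81 and 1.79 normalized counts. Higher values were SPCC11E10.09c 3.59, alr2 3.21, gst4 3.05, SPCC576.19c 2.99, SPCC1739.08c 2.84, sec72 2.64, SPCC576.02 2.57, SPAC29B12.14c 2.50, enp2 1.63, trr1 1.60, enp1 1.50, ctt1 1.11, trx2 0.59, pcs2 0.53 and ssz1 0.51. The exons of SPAPB1A11.03 lie wholly, and those of SPCC11E10.09c to 67.0%, opposite another gene, so both values are uncertain.

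The first pattern is that unstressed mutant cells resembled H2O2-treated wild type. Noise of the shared untreated wild-type libraries that is independent between genes and libraries is argued against as the whole cause, since the covariance was 0.458 and unchanged groups gave 0.0173. A deviation common to both untreated wild-type libraries was not simulated, so it stays open. Treated RNA carried into the untreated mutant libraries is argued against as the whole cause: the reads of pgr1 and ctt1 allow at most 2.27% from treated wild type and 1.46% from the treated mutant, and after removing either share 16 of the 18 core stress genes stayed called. Whether a stress-like expression state set by the loss of pgr1 accounts for it was not tested. The covariance with the mean response of both strains exceeded the simulated value by 0.339. In it, noise that is equal in the untreated libraries of both strains cancels, although the spread between these libraries was larger in wild type. But that covariance is the resemblance itself, so it gives no cause. With 1 deletion strain, another difference between the strains stays open.

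The second pattern is that respiratory chain transcripts fell while iron uptake transcripts rose in the untreated mutant. The scaling between libraries is argued against, as the list medians stayed at or below -1.22 and at or above 2.06 under 4 scalings, and so are reads of overlapping genes, since all 28 respiratory genes with at most 10% of their exons opposite another gene fell. Sparing of iron could explain both lists, but it does not account for ATP synthase, whose members carry no iron and had a median of -1.10. For the complexes that carry iron, the mean was -0.32 relative to ATP synthase (permutation test over 100000 resamples, two-sided, p = 0.041, adjusted over 5 comparisons 0.051). The test shuffled genes, which are not independent replicates, so its p-values measure the spread between genes and not between samples. Sparing of iron thus cannot be told apart there from a common fall of respiratory genes. Complex II, which carries iron, had a median of -0.73 and so fell less than ATP synthase. The gap was -0.54 between the strains after H2O2 (permutation test, adjusted p = 0.015), where the iron uptake list did not pass and complex II (-0.72) again fell less than ATP synthase (-1.04). It was -0.68 for H2O2 in the mutant, -0.46 for H2O2 in wild type and -0.22 for the difference of responses (permutation test, adjusted p = 0.0012, 0.0015 and 0.095). In wild type the pooled mean of the iron complexes was 0.16, against 0.62 for ATP synthase, but these complexes did not move together. Complex II fell there (median -0.51), while III (0.40) and IV (0.26) rose under the deposited scaling. Under quantile normalization the rise of the whole respiratory list was lost, so the rises of III and IV may depend on the scaling. With H2O2 in the mutant the medians were -0.54 for complex II, 0.12 for III, -0.21 for IV and 0.49 for ATP synthase.

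The third pattern is the smaller H2O2 induction of core stress genes in the mutant. The scaling between libraries is argued against, as the median difference of responses was at most -1.72 under 4 scalings, and the values of 1 library are argued against, as it was at most -1.69 with each library left out in turn. A higher untreated level with a common treated level cannot be told apart from other explanations: the median difference between the treated groups was 0.01 over the 20 genes, but 6 were called higher and 3 lower, and the difference of responses contains this value by construction. Untreated, the median difference was 1.64. As list medians, the smaller induction thus went with a higher untreated level and does not show lower treated levels.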

How the results depend on the processing

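The ribosomal protein list without RNase P subunits, and median centring, quantile normalization, edgeR and DESeq2 for single genes, were chosen after seeing the data, as were the sets of raised genes chosen on the mutant's or the mean response. The other alternatives were planned. Requiring a log2 fold change of at least 1 as well left 1286 genes for H2O2 in wild type, 884 for H2O2 in the mutant, 333 for the untreated mutant, 398 for the treated mutant and 339 for the difference of responses. Leaving out each library in turn gave 3376 to 3588, 2827 to 3478, 1351 to 2060, 1628 to 2488 and 781 to 1400 genes in that order, where the lone sample of a group is assumed to vary like the other groups. The lowest value for the treated mutant came without its replicate 2 (1628), and the difference of responses had 909 without replicate 1 and 781 without replicate 2 of the treated mutant, with the cause not tested. On recovered reads edgeR called 3649, 3443, 2008, 2408 and 1385 genes and DESeq2 3470, 3226, 1812, 2217 and 1212. With the replicate block the counts were 3822, 3638, 2345, 2794 and 1684; same-numbered libraries correlated between -0.14 and 0.37 in their deviations from group means, so the numbers do not establish pairs. camera with an estimated correlation called 0 lists in each of the 5 comparisons, with 3, 3, 3, 2 and 1 lists at an unadjusted p below 0.05, and fry called 22, 20, 18, 17 and 8. Pearson's r of the untreated mutant with the wild-type response ranged from 0.50 to 0.57 and with the mean response from 0.45 to 0.49 over left-out libraries; Spearman's rho was 0.46 and 0.45, and with a mean of at least 50 the second r was 0.49. Reversed under quantile normalization were gst2 (-0.25), grx4 (-0.26) and ura4 (-0.25) for H2O2 in the mutant and hsp16 (0.00) in the treated mutant, and the cause was not tested. For single genes 9081 values under alternatives kept direction and side of the threshold, 315 lost the call, 23 gained one and 4 reversed. For lists the numbers were 2327, 19, 39 and none. This tally of lists leaves out fry and camera with an estimated correlation, under which all list calls were lost. In simulated data 49.3% of changes of 1.5-fold in the difference of responses were recovered.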

Other observations

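The tests in this part were chosen after the data were seen, over 71 families of at least 8 tested genes sharing a 3-letter name (710 tests, Fisher's exact test, one-sided, Benjamini-Hochberg adjusted). Fisher's exact test takes genes as independent, but genes of a family can move together, so these p-values may be too small. Correlation between genes was not allowed for here. For the planned lists camera with an estimated correlation called none, but few lists could pass with it whatever the correlation. Autophagy genes (atg) rose in the untreated mutant in 22 of 28 cases and fell in 2, with a median log2 change of 0.53 (0.42 to 0.53 over 4 scalings, Fisher's exact test, adjusted p = 8.11e-08). Among the risers were atg8 (1.01 ± 0.08, SE, n = 2) and atg4 (1.11 ± 0.12). Autophagy genes also rose with H2O2 in wild type in 23 of 28 cases and fell in 1, with a median of 0.96 (Fisher's exact test, adjusted p = 7.3e-05). Genes of arginine metabolism and others named arg were lower in the treated mutant than in treated wild type in 9 of 10 cases, with a median of -0.58 (-0.65 to -0.58 over 4 scalings; Fisher's exact test, adjusted p = 3.8e-04), with arg5 at -1.03 ± 0.13 and arg3 at -0.92 ± 0.11. Pentatricopeptide repeat genes (ppr), most of whose products act on mitochondrial RNA, were lower there in 8 of 9 cases and higher in 1, with a median of -0.40 (-0.47 to -0.39 over 4 scalings, Fisher's exact test, adjusted p = 0.00129). The wtf genes, a family of meiotic drivers, were higher in the mutant in 21 of 25 cases untreated (median 1.05, but 0.66 with 17 higher and 1 lower under quantile normalization). After H2O2 23 of 25 were higher and 1 lower (median 1.38, 1.17 under quantile normalization). Fisher's exact test gave adjusted p = 4.76e-08 untreated and 5.79e-09 after H2O2, but the wtf sequences are similar, so reads could have been split between copies.

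Of the 283 genes raised at least 2-fold in the untreated mutant, 219 were also higher with H2O2 in wild type, 27 were lower and 37 were not called. The 27 include 7 wtf genes, with wtf22 at 2.33 ± 0.34 in the untreated mutant and -0.98 ± 0.34 with H2O2 in wild type. They also include the sulfate transporter gene sul2 (2.03 ± 0.11 in the untreated mutant, -1.53 ± 0.11 with H2O2 in wild type), cys2 of sulfur amino acid synthesis (1.71 ± 0.10 and -1.05 ± 0.10) and met1 (1.50 ± 0.14 and -1.42 ± 0.14), although the sulfur assimilation list did not pass in the untreated mutant (6 higher and 3 lower of 14, camera adjusted p = 0.528).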
